A study of Mus musculus with 12 samples.

How the data were processed

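The series holds polyA-selected RNA sequencing of peritoneal macrophages from C57BL/6 mice. Cells were lavaged with 7 ml of buffered saline, 3000000 were seeded per well and non-adherent cells were washed away after 2 h. TG mice received 3% thioglycollate, and IL4c mice received 5 ug of IL-4 with 25 ug of antibody per injection. The labels give no control protein for the SPARC wells, and untreated wells served as the reference.

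The authors deposited 2 matrices with 1 column per library. The first holds expected counts per gene made by the authors, not scaled, of which 7.97% are not whole numbers. The second holds FPKM values, which the authors scaled by gene length and library size. Per the submitters' processing notes the tools were CASAVA, bcl2fastq 1.8.4, STAR and RSEM. Genome build, annotation and the strandedness used in counting are not given in the sources used here. Of the 47729 gene identifiers, 98.9% match the GENCODE annotation of GRCm38 without the version suffix and 81.9% with it. Gene positions come from that annotation. Reads of near-identical genes may be shared by RSEM between copies, as for Saa1, Ly6c2, Ly6i, Oas1a, Chil3 and Chil4.

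Before the data were examined, the main fit, the alternatives, 31 gene lists and the rule for naming genes were fixed. Counts were rounded and fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM scaling and robust dispersion. Genes with low counts were removed by filterByExpr with a minimum count of 10, which left 15232. All 12 libraries were fitted in 4 groups with 8 residual degrees of freedom, and the common biological coefficient of variation was 0.308. Contrasts were SPARC against untreated in each injection, IL4c against TG in untreated wells, and the difference of the 2 SPARC contrasts. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values, as the cpm function of edgeR gives them, use TMM-scaled library sizes. Depth was 31501941 to 42288785 counts per library, so 3 counts correspond to between 0.0709 and 0.0952 CPM.

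Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, and adjusted over the 31 lists. They were also tested with an estimated correlation and with fry. With an estimated correlation, 4 lists had an unadjusted p under 0.05 in each SPARC comparison and 2 in each of the other comparisons, and none passed after adjustment. Members were also adjusted over their list alone.

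Alternatives were RLE and total-count scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a strict filter of 5 CPM in 3 libraries, log2 FPKM with pseudocounts of 1 and 0.1 on genes of at least 1 FPKM in 3 libraries, FPKM without a filter, the compared groups fitted alone, a fold minimum of 2, the replicate number as a block and each library left out. After the data were seen, fits without both TG libraries numbered 1 and without both IL4c libraries numbered 3 were added, as were camera tests with the block or without the TG pair. Numbers were read as pairing the libraries within an injection. Deviations from the group means of libraries with the same number in the same injection correlated at 0.342 to 0.735 in all 6 pairs. For different numbers in the same injection the range was −0.659 to 0.507, so the ranges overlap. Within an injection each library still correlated most with its own number in the other treatment. As the TG libraries numbered 1 stood apart, TG replicates 2 and 3 deviate alike whether paired or not. This pairing is read from the data, as the labels give only shared numbers. Across injections the range for the same number was −0.178 to 0.250, so numbers do not pair the libraries there. No 2 libraries of a group were copies, since their counts differed by a chi-square per degree of freedom of at least 10.6.

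The rule named the 6 largest rises and falls in each SPARC comparison and 8 of each between injections, among passing genes with a mean of at least 10 CPM and no overlap between the groups' libraries. It also took up to 4 members with the smallest p of each list described, and always Sparc, Tlr4, Ifnb1, Irf3, Irf7, Arg1, Mrc1, Retnla, Gata6, Tnf, Il6 and Il1b. Symbols of unsettled genes were passed over. Some genes that the rule named are not reported here. S100a9, Ltf, Ngp, Camp, Ighm, Il7r, the mitochondrial genes other than mt-Co3 and the genes under other observations fall outside the rule and were chosen after their values were seen.

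The fit was tested on simulated data with the same depth and gene-wise spread over 15232 genes. In each simulation 57 to 73 genes were changed at each fold, far fewer than the real fits called. The adjusted threshold was therefore stricter there, and the recoveries are not the power in these data. Libraries were drawn independently, without the pairing by number. In the TG comparison edgeR recovered 6.06% of genes changed 1.5-fold, 23.1% at 2-fold and 53.6% at 4-fold, with 1 false call among 57. In the IL4c comparison it recovered 12.9%, 35.1% and 72.6%, with 4 false calls among 86. Between the injections it recovered 6.25%, 37.9% and 60.0%, with 4 false calls among 75. In the TG simulation limma-voom made 4 false calls among 59 and DESeq2 41 among 141. Raw reads were not used here.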

Results

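Messenger RNA was sequenced from mouse peritoneal macrophages that had been drawn into, or expanded in, the peritoneal cavity in 2 ways and then kept for 24 h with or without SPARC at 20 ug/ml. SPARC is a secreted matricellular glycoprotein that binds collagen and other matrix components. Thioglycollate (TG), an irritant broth that recruits inflammatory monocytes, was given to C57BL/6 mice 4 days before collection. IL-4 complex (IL4c), the cytokine IL-4 held by an antibody that prolongs its action, was given in 2 injections, the last of them 2 days before collection. The 12 libraries formed 4 groups of 3: TG untreated, TG with SPARC, IL4c untreated and IL4c with SPARC. Each library held 31501941 to 42288785 estimated gene counts, and 15232 genes passed the filter on low counts. The labels do not state that replicates came from separate animals, so p-values measure the spread between these samples, whatever its source. Levels are counts scaled to library size (CPM) as mean ± SD with n = 3 libraries per group, and fold changes are log2 values ± SE. The SE was taken as the absolute log2 fold change divided by the square root of the F statistic of the test.

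The comparison of TG macrophages with and without SPARC asked whether the protein changes gene expression, and in particular the interferon response, in recruited macrophages. Interferon-stimulated genes, which encode antiviral effectors and their regulators, were higher with SPARC. Irf7, a transcription factor that amplifies the type I interferon response (ENSMUSG00000025498.14, protein coding, GRCm38 chromosome 7, 141262706 to 141266481, minus strand), went from 30.7 ± 15.9 to 824 ± 55.3 CPM, a rise of 4.75 ± 0.35 (adjusted p = 1.60e-04). Isg15, a ubiquitin-like modifier (ENSMUSG00000035692.6, protein coding, chromosome 4, 156199424 to 156200818, minus strand), rose by 4.22 ± 0.23 from 4.34 ± 1.08 CPM (adjusted p = 3.60e-05). Bst2, which tethers budding viruses, rose by 3.08 ± 0.21, and Oas1a, an enzyme that activates RNA decay after sensing double-stranded RNA, by 2.10 ± 0.14. Of the 51 tested members of the fixed interferon list, 48 rose (50 adjusted over the list alone), with a median of 2.25. The list stood above the other genes in the camera test (adjusted p = 5.87e-48; adjusted p = 0.207 with an estimated correlation). The list of MHC class I presentation genes, which load peptides for cytotoxic T cells, had 18 of 21 members higher (20 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.40e-15; adjusted p = 0.227 with an estimated correlation). H2-T22 rose by 1.81 ± 0.19 and Tapbp, a chaperone of class I molecules, by 1.56 ± 0.21. With the TG libraries fitted alone, 3 of the 21 MHC class I genes passed.

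Genes of inflammation and of glucose use were also higher in TG macrophages with SPARC. The chemokine gene Ccl5 (ENSMUSG00000035042.2, protein coding, chromosome 11, 83525778 to 83530518, minus strand) went from 11.4 ± 9.48 to 715 ± 104 CPM, a rise of 5.96 ± 0.60 (adjusted p = 6.53e-04). In the list of NF-kB cytokines and feedback genes, 13 of 37 members rose (21 adjusted over the list alone, 24 with the replicate number as a block), with a median of 1.10. Among them, Irg1 (also called Acod1), which makes itaconate, rose by 4.25 ± 0.62 and Ccl2, a monocyte chemoattractant, by 3.27 ± 0.47. The list passed camera (adjusted p = 2.68e-11; adjusted p = 0.256 with an estimated correlation). Its count was 7 without TG untreated replicate 2, 6 without TG untreated replicate 3 and 8 without TG SPARC replicate 1. Of 25 glycolysis genes, 17 rose (20 adjusted over the list alone), with a median of 1.40 (camera adjusted p = 1.96e-13; adjusted p = 0.208 with an estimated correlation). The liver-type phosphofructokinase gene Pfkl rose by 1.62 ± 0.18 from 113 ± 9.14 CPM, and the hexokinase gene Hk2 by 1.66 ± 0.19. Tnf rose by 1.69 ± 0.42 (adjusted p = 0.0312) and Il1b by 4.09 ± 1.02 (adjusted p = 0.0303). The Tnf call was lost without any 1 of TG untreated replicates 2 and 3 and TG SPARC replicates 2 and 3 (adjusted p from 0.0631 to 0.111). The Il1b call was lost without TG untreated replicate 2 or 3, TG SPARC replicate 1 or IL4c untreated replicate 2 (adjusted p from 0.0501 to 0.0953). Il6 stood at 2.15 ± 1.18 and did not pass (adjusted p = 0.282).

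The list of interferon-gamma-type GTPases and targets had 7 of 21 members higher in TG macrophages with SPARC (17 adjusted over the list alone, 16 with the replicate block), with a median of 1.90. Socs1, a feedback inhibitor of cytokine signalling, rose by 3.78 ± 0.39 (adjusted p = 6.87e-04). The list passed camera (adjusted p = 7.79e-10; adjusted p = 0.411 with an estimated correlation). Its count was 11 without TG untreated replicate 2, 1 without TG SPARC replicate 2 and 3 without TG SPARC replicate 3. Of 25 genes for matrix proteins and SPARC receptors, 4 rose and 1 fell, the same numbers as when adjusted over the list alone, while the replicate block called 8 and 2 (camera adjusted p = 0.0197; adjusted p = 0.411 with an estimated correlation). The protease inhibitor gene Timp1 rose by 5.26 ± 0.47, and the membrane protease gene Mmp14 rose by 1.59 ± 0.13. Of 35 nuclear genes for oxidative phosphorylation, 6 rose (9 adjusted over the list alone, 23 with the replicate block), with a median of 0.28 (camera adjusted p = 5.90e-07; adjusted p = 0.629 with an estimated correlation). Leaving out single libraries gave from 0 such genes (TG untreated replicate 3 or TG SPARC replicate 3) to 10 (IL4c untreated replicate 3). Of 22 unfolded protein response genes, 3 rose and 1 fell (8 and 2 adjusted over the list alone, 9 and 3 with the replicate block), and 7 rose without TG untreated replicate 1. That list passed camera (adjusted p = 0.0229; adjusted p = 0.411 with an estimated correlation). Its chaperone genes Hsp90b1, at 0.63 ± 0.14, and Hyou1, at 0.86 ± 0.20, lost their calls without TG untreated replicate 3 (adjusted p = 0.0689 and 0.0716). Without both TG libraries numbered 1 the matrix and the unfolded protein response lists did not pass camera. Genes that sense nucleic acids or carry the interferon signal did not pass as a list (6 of 22 higher and 1 lower, 6 and 2 adjusted over the list alone, camera adjusted p = 0.224), and 3 were higher without TG untreated replicate 2 or 3. Ifnar2, a subunit of the type I interferon receptor, rose by 1.01 ± 0.12, and the kinase gene Tbk1 by 0.46 ± 0.08.

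Among TG macrophage genes with a mean of at least 10 CPM and no overlap between treated and untreated libraries, the largest rise was that of Lcn2, an iron-sequestering acute-phase protein, at 6.10 ± 1.17 (adjusted p = 0.0114). Its level was 1215 CPM in TG SPARC replicate 1, 172 in replicate 2 and 209 in replicate 3. The Lcn2 estimate was 4.68 without TG SPARC replicate 1 and 7.91 without TG untreated replicate 1. With any 1 library left out Ccl5 stood at 5.65 or more, so Lcn2 fell below it without TG SPARC replicate 1. Without TG untreated replicate 1 Lcn2 fell below Ly6c2, at 8.09. The first rank of Lcn2 thus rests on both of these libraries. Ccl5 came next, followed by Ifi44, which rose by 5.53 ± 0.60, and by Saa1, Ly6c2 and Ly6i. Saa1, an acute-phase gene with a near-identical copy, rose by 5.28 ± 1.45 (adjusted p = 0.0436), a call that was lost in 10 of the 12 fits that each left out 1 library (adjusted p from 0.0508 to 0.150). Ly6c2, a monocyte surface antigen, rose by 5.27 ± 1.26, and its call was lost without TG untreated replicate 2 or 3 or TG SPARC replicate 2 or 3 (adjusted p from 0.0537 to 0.0688). Ly6i rose by 5.27 ± 1.09, and its estimate was 7.91 without TG untreated replicate 1, while those of Ly6c2 and Saa1 were then 8.09 and 7.83. Without TG SPARC replicate 1, Saa1 stood at 3.10. The largest falls were in Cbr2, a carbonyl reductase, by 3.32 ± 0.67, and in the lectin receptor gene Clec10a, by 3.15 ± 0.36. Engase fell by 3.14 ± 0.49, Gas6, a bridging ligand for the uptake of dying cells, by 2.80 ± 0.51, Gpx3 by 2.76 ± 0.40 and Slc46a3 by 2.31 ± 0.29.

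Genes of alternative activation, the programme that IL-4 induces, moved in both directions in TG macrophages with SPARC: 3 of 30 rose and 2 fell (4 and 2 adjusted over the list alone, 8 and 8 with the replicate block). Without TG untreated replicate 1 there were 5 higher. The list's median of −0.17 and its camera direction were negative and its mean of 0.06 positive (camera adjusted p = 0.936). Arg1, which encodes an arginine-degrading enzyme (ENSMUSG00000019987.8, protein coding, chromosome 10, 24915221 to 24927484, minus strand), went from 215 ± 102 to 1261 ± 173 CPM, a rise of 2.55 ± 0.46 (adjusted p = 0.00855). The mannose receptor gene Mrc1 stood at −2.02 ± 0.85 (adjusted p = 0.161, and 0.00974 with the replicate block). Retnla stood at −0.29 ± 0.67 and Gata6, the transcription factor of large resident peritoneal macrophages, at −0.80 ± 0.49 (adjusted p = 0.339, and 0.0446 with the block). In the large resident macrophage list 1 of 20 genes was higher, in the cholesterol list 1 of 23 was lower and in the list of liver X receptor targets 3 of 12 were higher. Adjusted over each list alone, these were 2 higher and 2 lower, 1 lower and 3 higher. With the block, 4 large resident genes were higher and 5 lower, 2 cholesterol genes were higher and 2 lower, and 4 liver X receptor targets were higher and 3 lower. In the large resident list 4 genes and in the cholesterol list 3 were higher without TG untreated replicate 1, and no large resident gene was higher without TG untreated replicate 3. Among fatty acid oxidation genes 1 of 20 was higher and 5 were lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.140), with 0 lower without TG SPARC replicate 3, 3 higher without TG untreated replicate 1 and 4 higher with the block. Sparc itself stood at 0.16 ± 1.04 (adjusted p = 0.948), Tlr4 at −0.06 ± 0.12 (adjusted p = 0.814) and Irf3 at −0.26 ± 0.10 (adjusted p = 0.138). Irf3 passed without TG SPARC replicate 1 (adjusted p = 0.0356). Ifnb1, the gene of interferon beta, had at most 1 count in any library and was not tested.

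Markers of other cells were measured beside these genes. Of 7 neutrophil genes, 2 rose (3 adjusted over the list alone, 4 with the replicate block), among them S100a8 by 2.07 ± 0.29 (camera adjusted p = 0.008; adjusted p = 0.411 with an estimated correlation). S100a9, abundant in neutrophils, had at most 3 counts in any library, with or without SPARC, although S100a8 had at least 210 in each. Of 14 monocyte and small macrophage genes, among them Ly6c2, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.85, and the list did not pass (camera adjusted p = 0.0628). It passed without both TG libraries numbered 1 (adjusted p = 0.00690) and with the replicate block, where 6 were higher (camera adjusted p = 0.0185; adjusted p = 0.441 with an estimated correlation). The higher genes numbered 2 without TG untreated replicate 2 or 3 or TG SPARC replicate 2. The lower genes numbered 2 without TG untreated replicate 1 and 0 without TG SPARC replicate 1 or 3. The TG libraries numbered 1 stood apart from the other TG libraries on the third principal component, at −82.4 untreated and −81.7 with SPARC. The 15 tested B cell genes summed to 2682 and 2052 CPM in that pair, against 187 to 305 CPM in the other 4 TG libraries. With the replicate block 11 of these 15 genes fell with SPARC (camera adjusted p = 1.80e-07; adjusted p = 0.341 with an estimated correlation), and without the block the list did not pass (adjusted p = 0.236).

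Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1714 genes in TG macrophages, 1025 higher and 689 lower with SPARC. At least a 2-fold change was seen in 500 of the higher and 186 of the lower genes. The 3 SPARC libraries all lay on one side of the 3 untreated libraries for 1709 of the called genes, and for 30.4% of all tested genes. Chance gives 10% if the libraries are exchangeable, which pairing by number would alter, and calling a gene itself favours such separation. With the replicate block 4165 genes passed (2175 higher and 1990 lower), and with the TG libraries fitted alone 505 (367 higher and 138 lower). Without TG untreated replicate 2 or 3 the count was 1067 or 737, and without TG SPARC replicate 2 or 3 it was 970 or 965. The balance of calls turned under other scalings: 758 higher and 938 lower by total counts, and 752 higher and 828 lower on log2(FPKM + 1) values.

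**Figure D1:**
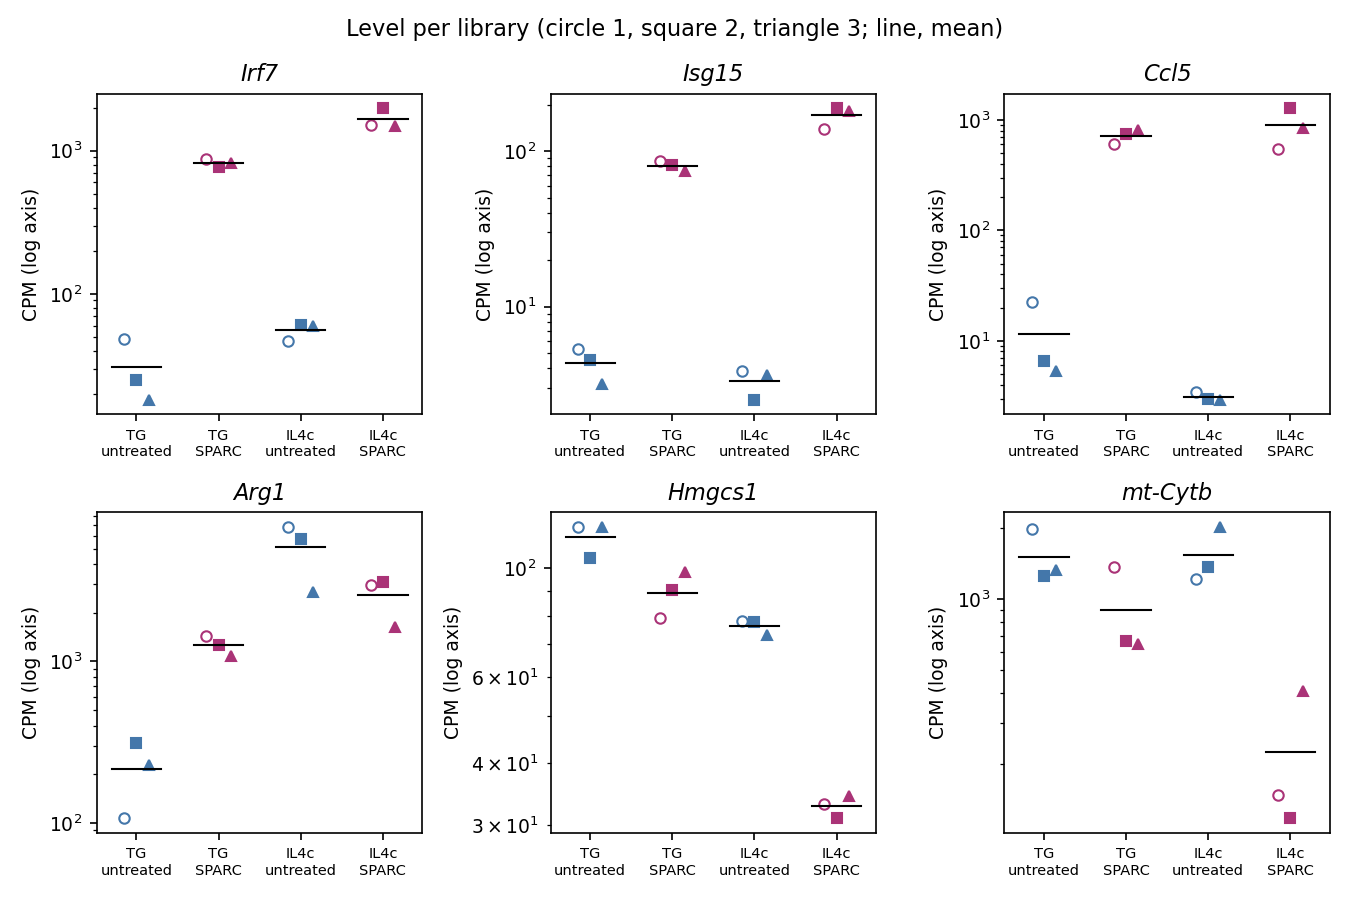
Level of 6 genes in each of the 12 libraries, in CPM on a log axis; symbols show the replicate number (circle 1, square 2, triangle 3) and the line is the mean of each group of 3. Irf7 reached 824 CPM with SPARC after TG and 1666 CPM with SPARC after IL4c, while Hmgcs1 went from 76.3 to 32.8 CPM after IL4c.

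The same comparison in IL4c macrophages asked how SPARC acts on cells expanded and polarised by IL-4. All 51 tested interferon-stimulated genes rose (51 adjusted over the list alone), with a median of 3.50 (camera adjusted p = 9.44e-38; adjusted p = 0.240 with an estimated correlation). Irf7 went from 55.6 ± 7.67 to 1666 ± 275 CPM, a rise of 4.90 ± 0.35 (adjusted p = 3.97e-05). Isg15 rose by 5.68 ± 0.24 (adjusted p = 3.93e-06) and Oas3, an activator of antiviral RNA decay, by 5.31 ± 0.28. All 21 MHC class I presentation genes rose (21 adjusted over the list alone), with a median of 1.88 (camera adjusted p = 5.50e-15; adjusted p = 0.240 with an estimated correlation). H2-T22 rose by 3.14 ± 0.20 and the immunoproteasome gene Psmb8 by 2.18 ± 0.21. Of the 21 interferon-gamma-type GTPases and targets, 17 rose and 1 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 1.35e-05; adjusted p = 0.519 with an estimated correlation). The GTPase gene Irgm1 rose by 2.56 ± 0.48 and Socs1 by 3.13 ± 0.40, while Irf8, a transcription factor of the monocyte lineage, fell by 1.38 ± 0.26. The number of higher members was 11 without IL4c untreated replicate 1 or 3 and 10 without replicate 2.

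Inflammatory and glycolytic genes rose in IL4c macrophages too. Of 37 NF-kB cytokine and feedback genes, 18 rose (23 adjusted over the list alone), with a median of 1.77 (camera adjusted p = 1.53e-08; adjusted p = 0.348 with an estimated correlation). Ccl2 rose by 4.31 ± 0.49 and Tnfaip3, an inhibitor of NF-kB signalling, by 1.91 ± 0.20. Tnf rose by 2.03 ± 0.44 (adjusted p = 0.00751). Il6 stood at 2.47 ± 1.13 (adjusted p = 0.133, and 0.0253 with the replicate block) and Il1b at 2.63 ± 0.98 (adjusted p = 0.0729, and 0.00552 with the block). Both passed without TG SPARC replicate 1 (adjusted p = 0.0413 and 0.0405). Without both IL4c libraries numbered 3, the number of higher NF-kB genes was 10 and Tnf did not pass. Of 25 glycolysis genes, 13 rose (16 higher and 1 lower adjusted over the list alone, 22 higher with the replicate block), with a median of 0.95. The list passed camera (adjusted p = 2.00e-05; adjusted p = 0.413 with an estimated correlation). The hexokinase genes Hk1 and Hk2 rose by 0.67 ± 0.10 and 1.29 ± 0.19. For nuclear genes of oxidative phosphorylation, 5 of 35 were higher and 1 lower (5 and 1 adjusted over the list alone), and 13 were higher with the replicate block. That list passed camera with the block (adjusted p = 0.0479; adjusted p = 0.610 with an estimated correlation) and not without it (adjusted p = 0.108). Its count of higher genes was 3 without IL4c untreated replicate 1 or 2 or IL4c SPARC replicate 3, and 11 without IL4c untreated replicate 3.

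Lists of cholesterol synthesis and of fatty acid oxidation lay lower with SPARC in IL4c macrophages, and the list of liver X receptor targets lay higher. Of 23 genes for cholesterol synthesis and uptake, 15 fell (19 lower and 1 higher adjusted over the list alone), with a median of −0.84. The list lay below the other genes (camera adjusted p = 1.46e-08; adjusted p = 0.319 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate (ENSMUSG00000093930.1, protein coding, chromosome 13, 119690379 to 119708260, plus strand), went from 76.3 ± 2.76 to 32.8 ± 1.72 CPM, a fold change of −1.22 ± 0.09 (adjusted p = 4.87e-05). Idi1, an isomerase of the same pathway, fell by 1.96 ± 0.23, and Stard4, a cholesterol carrier, by 1.82 ± 0.22. Of 20 fatty acid oxidation genes, 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 4.33e-04; adjusted p = 0.240 with an estimated correlation). The thiolase gene Acaa2 fell by 1.20 ± 0.12, the dehydrogenase gene Acadm by 0.50 ± 0.06 and Cpt1a, which admits fatty acids to mitochondria, by 1.00 ± 0.13. The number of lower members was 7 without IL4c untreated replicate 2 or 3 or IL4c SPARC replicate 1 or 2. Of 12 liver X receptor targets, 5 rose and 1 fell (6 and 1 adjusted over the list alone, 8 and 1 with the replicate block), with a median of 0.80 (camera adjusted p = 0.0446; adjusted p = 0.416 with an estimated correlation). Nr1h3, which encodes the receptor itself, rose by 2.31 ± 0.28 and the desaturase gene Scd2 by 3.24 ± 0.36, while Apoe, the lipid carrier, fell by 1.76 ± 0.38.

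The list of phagocytosis and lysosome genes did not pass in IL4c macrophages (5 of 31 higher and 7 lower, 5 and 7 adjusted over the list alone, camera adjusted p = 0.190). With the replicate block 8 were higher and 15 lower (camera adjusted p = 0.0479; adjusted p = 0.610 with an estimated correlation), and without IL4c SPARC replicate 1 the number of lower genes was 4. Mertk, a receptor for the uptake of dying cells, fell by 1.61 ± 0.18 from 340 ± 44.5 CPM, and Gas6, its ligand, fell by 3.60 ± 0.52. Axl, a receptor of the same family, rose by 3.35 ± 0.43 from 6.23 ± 1.94 CPM. Among 30 alternative activation genes 5 were higher and 4 lower (5 and 5 adjusted over the list alone), with a median of −0.51 (camera adjusted p = 0.230). With the block 7 were higher and 15 lower (camera adjusted p = 0.0479; adjusted p = 0.400 with an estimated correlation), while the higher genes numbered 0 without IL4c untreated replicate 2 and the lower genes 1 without IL4c SPARC replicate 1. Arg1 stood at −0.98 ± 0.44 (adjusted p = 0.123, and 0.0492 with the block). Mrc1 stood at −2.31 ± 0.86 (adjusted p = 0.0708, and 0.00215 with the block), and it passed without IL4c SPARC replicate 3 (adjusted p = 0.0111). Retnla stood at −0.28 (adjusted p = 0.795), Gata6 at 0.03 (adjusted p = 0.975), Sparc at 0.04 ± 1.18 (adjusted p = 0.986), Tlr4 at −0.15 (adjusted p = 0.377) and Irf3 at −0.18 (adjusted p = 0.228). In the large resident macrophage list 3 of 20 genes were lower (2 adjusted over the list alone, 9 with the block), among them Vsig4, a complement receptor, at −3.89 ± 0.71. Without IL4c SPARC replicate 1 or 2 the count was 1.

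The largest rise among the more abundant, separated genes of IL4c macrophages was in Apol9b, an interferon-inducible apolipoprotein L gene with a close paralog, by 8.64 ± 1.10 from 0.102 ± 0.115 CPM (adjusted p = 5.61e-04). Ccl5 rose by 8.16 ± 0.67 from 3.11 ± 0.259 to 889 ± 370 CPM, Saa1 by 7.87 ± 1.36 and Lcn2 by 7.82 ± 1.26. Ifi44 rose by 7.58 ± 0.62, and Dgat2, which completes triglyceride synthesis, by 7.16 ± 1.34. The largest falls were in Cbr2, by 5.21 ± 0.74, Nxpe5, by 4.19 ± 0.58, Arhgap19, by 4.17 ± 0.71, and Vsig4. The mitochondrially encoded mt-Co3 fell by 3.85 ± 1.28 (adjusted p = 0.0482), and its call was lost in 10 of the 12 fits that each left out 1 library (adjusted p from 0.0501 to 0.140). Hpgds, a prostaglandin D synthase, fell by 3.62 ± 0.87, and its call was lost without IL4c SPARC replicate 1 or 2 (adjusted p = 0.0543 at most). Mitochondrially encoded genes took 0.522% to 1.09% of the counts in IL4c libraries with SPARC and 1.62% to 2.42% in those without. The B cell list did not pass (camera adjusted p = 0.0987), while 14 of its 15 genes were lower with the replicate block (camera adjusted p = 4.11e-08; adjusted p = 0.387 with an estimated correlation). Of 7 neutrophil genes 3 were higher (3 adjusted over the list alone), and the list passed camera with the block (adjusted p = 0.036; adjusted p = 0.387 with an estimated correlation) and not without it (adjusted p = 0.0905). Eosinophil genes had a median of −2.37, with 1 of 5 lower (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0987). With the block all 5 were lower (camera adjusted p = 0.0191; adjusted p = 0.387 with an estimated correlation). None was lower without IL4c untreated replicate 2 or 3 or IL4c SPARC replicate 3. The 5 genes summed to 39.2 to 270 CPM untreated and 9.39 to 51.8 CPM with SPARC. Of 10 fibroblast and endothelial genes 3 were higher (3 adjusted over the list alone), and 5 were higher and 1 lower with the block. That list did not pass (camera adjusted p = 0.108).

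The cell cycle and unfolded protein response lists did not pass in IL4c macrophages (camera adjusted p = 0.525 and 0.108) and passed with the block (camera adjusted p = 0.0479 each; adjusted p = 0.610 each with an estimated correlation). With the block 3 of 35 cell cycle genes were higher and 13 lower. Without the block edgeR called 0 of them, also adjusted over the list alone, with 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. There were 2 higher without IL4c untreated replicate 3 and 3 lower without IL4c SPARC replicate 3. In those 2 libraries the cell cycle genes summed to 771 and 768 CPM, against 292 to 355 CPM in the other IL4c libraries. Both also stood apart on the fourth principal component, at 42.5 and 46.7 against −24.0 to −11.0. The unfolded protein response list had 7 of 22 genes higher and 3 lower, the same as when adjusted over the list alone, and 11 and 4 with the block. Its higher genes numbered 3 without IL4c untreated replicate 1 or IL4c SPARC replicate 3, 2 without IL4c untreated replicate 2 and 4 without IL4c SPARC replicate 2, and its lower genes 1 without any of these 4 libraries.

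In IL4c macrophages edgeR called 4237 genes, 2301 higher and 1936 lower with SPARC, of which 1004 and 729 changed at least 2-fold. The libraries of the groups did not overlap for 4200 of the called genes and for 50.4% of those tested, where chance gives 10% if the libraries are exchangeable. The replicate block gave 6880 calls (3474 higher and 3406 lower). Without IL4c untreated replicate 2 there were 2507 calls, without both IL4c libraries numbered 3 there were 2679 and without both TG libraries numbered 1 there were 6507.

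**Figure D2:**
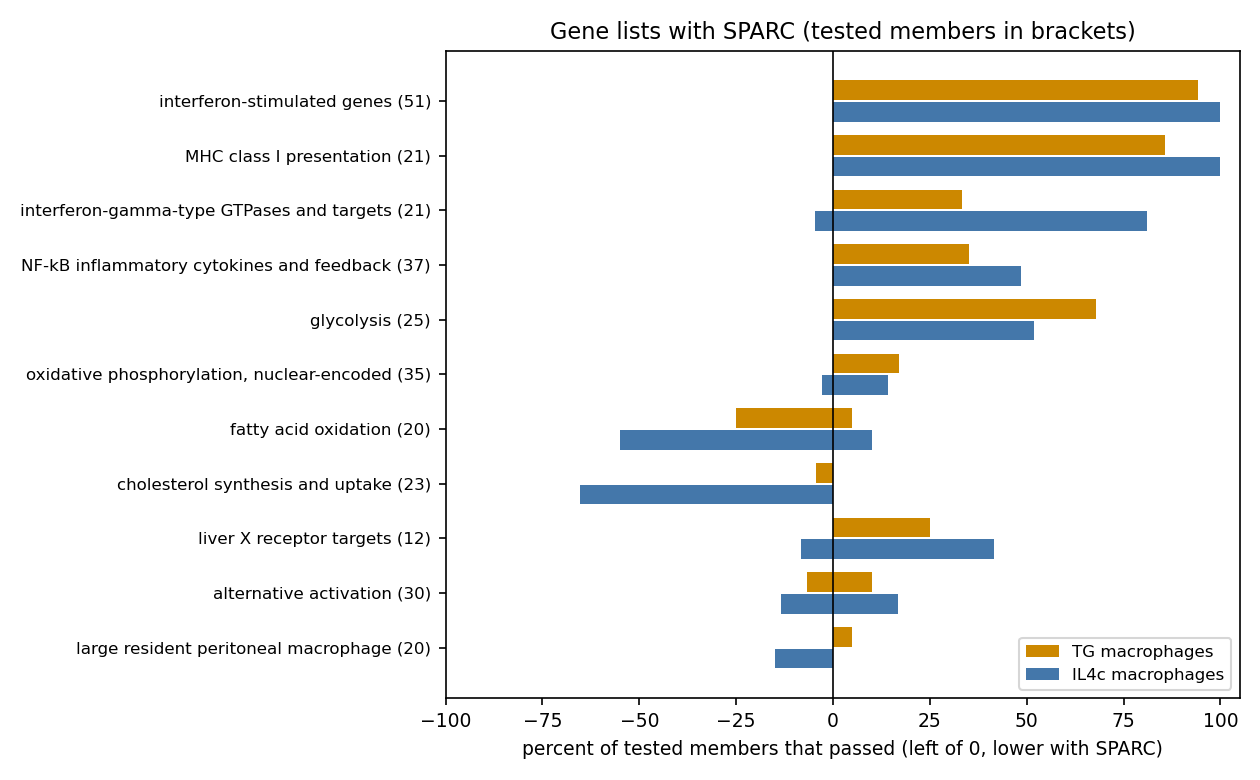
Percent of the tested members of 11 fixed gene lists that passed with SPARC, to the right of 0 where higher and to the left where lower, in TG and IL4c macrophages; the number of tested members stands in brackets. All 51 interferon-stimulated genes passed after IL4c and 48 after TG, and 15 of the 23 cholesterol genes were lower after IL4c.

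Untreated macrophages of the 2 injections were compared to describe the cells without SPARC. Genes of alternative activation were higher after IL4c: 9 of 30 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 5.77e-04; adjusted p = 0.618 with an estimated correlation). The chitinase-like gene Chil3 (ENSMUSG00000040809.10, protein coding, chromosome 3, 106147554 to 106167564, minus strand), which shares sequence with Chil4, stood at 17.2 ± 13.9 CPM after TG and 29988 ± 5450 after IL4c, a difference of 10.77 ± 0.87 (adjusted p = 1.94e-04). Chil4 had no counts in the TG untreated libraries and 82.3 ± 19.8 CPM after IL4c, at least 1010-fold higher than the floor of 3 counts per library. Such floors cover counting error only. Retnla, a secreted product of IL-4-stimulated macrophages, was higher by 6.91 ± 0.87, Arg1 by 4.56 ± 0.50 and the arginine transporter gene Slc7a2 by 4.69 ± 0.55. Without TG untreated replicate 1 the number of higher members was 15. Of 20 large resident macrophage genes, 12 were higher (14 adjusted over the list alone), with a median of 2.52 (camera adjusted p = 1.15e-07; adjusted p = 0.661 with an estimated correlation). Gata6 was higher by 2.75 ± 0.50, Rarb, a retinoic acid receptor, by 2.96 ± 0.26, Garnl3 by 3.62 ± 0.64 and the coagulation factor gene F10 by 1.97 ± 0.31. The number was 7 without TG untreated replicate 2 and 6 without replicate 3.

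Several metabolic lists differed between the injections. Cholesterol genes were lower after IL4c in 11 of 23 cases (14 adjusted over the list alone), with a median of −0.51 (camera adjusted p = 8.37e-05; adjusted p = 0.816 with an estimated correlation). Hmgcs1 stood at −0.60 ± 0.09. The count was 7 without IL4c untreated replicate 1 or 3 and 6 without replicate 2. Of 20 fatty acid oxidation genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00336; adjusted p = 0.618 with an estimated correlation). Acadl was higher by 0.70 ± 0.12 and Etfa, an electron carrier, by 0.60 ± 0.09. By total counts or on FPKM values 5 fatty acid oxidation genes were higher. Of 22 TCA cycle genes 5 were higher (7 adjusted over the list alone, camera adjusted p = 5.77e-04; adjusted p = 0.818 with an estimated correlation), among them Idh1, from 406 ± 29.9 to 815 ± 39.8 CPM. Glycolysis genes were higher in 5 and lower in 2 of 25 cases (6 and 2 adjusted over the list alone, camera adjusted p = 0.0271; adjusted p = 0.818 with an estimated correlation), with 1 higher without IL4c untreated replicate 1 or 2, and the list did not pass without both TG libraries numbered 1.

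Interferon-related lists lay lower after IL4c in untreated cells by camera, and none of the 3 passed without both TG libraries numbered 1. In mean log2 CPM, TG untreated replicate 3 lay below all IL4c untreated libraries for interferon-stimulated genes (3.66 against 3.87 to 3.99). The same held for the GTPase list (2.42 against 2.89 to 3.18), and for MHC class I it lay among them (6.68 against 6.59 to 6.70). TG untreated replicates 1 and 2 lay above them, at 4.72 and 4.35, 4.52 and 5.19, and 7.38 and 7.45. MHC class I presentation genes were lower in 6 of 21 cases (9 adjusted over the list alone), with a median of −0.72 (camera adjusted p = 0.00188; adjusted p = 0.818 with an estimated correlation). Of the interferon-stimulated genes 2 were higher and 9 lower, the same as when adjusted over the list alone, with a median of −0.45 (camera adjusted p = 0.0412; adjusted p = 0.864 with an estimated correlation). Of the interferon-gamma-type GTPases and targets 1 was higher and 6 lower (1 and 9 adjusted over the list alone), with a median of −1.42 (camera adjusted p = 0.0467; adjusted p = 0.863 with an estimated correlation). Without IL4c untreated replicate 1 these 3 lists had 0, 1 and 0 lower members, and without TG untreated replicate 3 they had 10, 17 and 15. Without TG untreated replicate 1 the interferon list had 6 higher members. Irf7 stood at 0.86 ± 0.30 (adjusted p = 0.0704) and passed without TG untreated replicate 1 (adjusted p = 0.00175). Tlr4 stood at 0.35 (adjusted p = 0.0612) and passed without TG SPARC replicate 1 (adjusted p = 0.0427). Irf3 was lower, at −0.34 ± 0.10 (adjusted p = 0.0434), a call lost in 9 of the 12 fits that each left out 1 library (adjusted p from 0.0548 to 0.145). Tnf was lower, at −1.58 ± 0.43 (adjusted p = 0.0295), a call lost without TG untreated replicate 2 or IL4c untreated replicate 2 or 3 (adjusted p from 0.0881 to 0.111). Il6 stood at 1.58 (adjusted p = 0.367), Il1b at −1.08 (adjusted p = 0.451) and Mrc1 at 0.38 (adjusted p = 0.776).

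Beyond the chitinase-like genes and Retnla, the largest differences in favour of IL4c were in Rnase2a, a ribonuclease with close paralogs, at 9.04 ± 1.09, and in the chemokine receptor gene Ackr3, at 7.54 ± 1.20. The channel genes Aqp9 and Kcnn3 stood at 5.36 ± 0.49 and 5.28 ± 1.16. Lrg1 stood at 5.14 ± 1.46 (adjusted p = 0.0335), with its call lost without TG untreated replicate 2 or 3 or IL4c untreated replicate 1 or 2 (adjusted p from 0.0830 to 0.0917) and an estimate of 8.47 without TG untreated replicate 1. The largest differences in favour of TG were in Ly6c2, at −5.70 ± 1.73 (adjusted p = 0.0419), and in the collagen gene Col1a1, at −4.76 ± 1.21 (adjusted p = 0.0224). The Ly6c2 call was lost in 9 of the 12 fits that each left out 1 library (adjusted p from 0.0515 to 0.186), and the estimate was −2.87 without TG untreated replicate 1. The Col1a1 call was lost without TG untreated replicate 2 or 3 or IL4c untreated replicate 1 or 2 (adjusted p from 0.0603 to 0.0881). Ms4a6b stood at −4.62 ± 0.83, the Fc receptor gene Fcgr1 at −4.06 ± 0.48, Pianp at −3.67 ± 0.74 and Coro1a, an actin-binding protein of leukocytes, at −3.65 ± 0.23. Adam19 and Ggta1 stood at −3.63 ± 0.40 and −3.55 ± 0.69. Sparc itself was lower after IL4c, at −4.22 ± 1.22 (adjusted p = 0.0359), a call lost in 9 of the 12 such fits (adjusted p from 0.0527 to 0.126). Of 10 genes of fibroblasts and endothelium, among them Col1a1, 2 were lower (7 adjusted over the list alone), with a median of −2.25. That list did not pass (camera adjusted p = 0.0857) and passed without both TG libraries numbered 1 (adjusted p = 0.00680). Its lower genes numbered 6 without TG untreated replicate 1, 5 without TG SPARC replicate 1 and 1 without TG SPARC replicate 3 or any IL4c SPARC replicate. None was lower without TG untreated replicate 2 or 3 or IL4c untreated replicate 1 or 2. Among monocyte and small macrophage genes 4 of 14 were lower (6 lower and 1 higher adjusted over the list alone), and the list did not pass (camera adjusted p = 0.151). The integrin gene Itgal stood at −3.40 ± 0.31 and the chemokine receptor gene Ccr2 at −3.19 ± 0.39. Mast cell genes were higher after IL4c in 2 of 9 cases (6 adjusted over the list alone), with a median of 3.35 (camera adjusted p = 0.0412; adjusted p = 0.818 with an estimated correlation), in 4 without IL4c untreated replicate 2 and in 0 without IL4c untreated replicate 1 or TG untreated replicate 2 or 3. Levels were low: the 9 genes together summed to 2.32 to 3.61 CPM in TG untreated libraries. In IL4c untreated replicates 1, 2 and 3 they summed to 21.1, 2.84 and 5.62 CPM. The list of T and NK cell genes lay below the other genes, with a median of −2.18 (camera adjusted p = 0.0256; adjusted p = 0.818 with an estimated correlation). By edgeR 0 of its 14 genes passed, also adjusted over the list alone, while 2 had an unadjusted p under 0.05. DESeq2 called 1 of them and limma-voom 0, and edgeR called 1 without TG untreated replicate 1 or TG SPARC replicate 1. Neither the mast cell nor the T and NK cell list passed without both TG libraries numbered 1.

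Between the untreated groups edgeR called 3197 genes, 1548 higher and 1649 lower after IL4c, of which 804 and 438 differed at least 2-fold. The libraries of the groups did not overlap for 3100 of the called genes and for 39.0% of those tested, where chance gives 10% if the libraries are exchangeable. By total counts 1154 genes were higher and 2790 lower, and on log2(FPKM + 1) values 933 and 2421, while the median over all genes moved from −0.05 to −0.16 under total counts. Without the low-count filter 1367 were higher and 922 lower. The count was 1376 without TG untreated replicate 2, 1699 without TG untreated replicate 3, 1516 without IL4c untreated replicate 1 and 1587 without IL4c untreated replicate 2. Without both TG libraries numbered 1 it was 6002, and with the 2 untreated groups fitted alone 1631 (1034 higher and 597 lower).

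The responses to SPARC after the 2 injections were compared to ask whether they differ. Across the 15232 genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.711 and a Spearman rho of 0.687. Of the genes called in TG macrophages 98.2% had the same sign in IL4c macrophages, and of those called in IL4c macrophages 93.8% had the same sign in TG macrophages. Over all tested genes this share was 76.7%. Both responses shared 835 higher genes, where independent lists of these lengths would share 155, and 556 lower genes, where they would share 87.6. The 2 comparisons have no library in common, but both use the spread from 1 fit, so genes are not equally likely to be called. Without TG untreated replicate 1 the Pearson r was 0.573 and without TG SPARC replicate 1 it was 0.567.

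**Figure D3:**
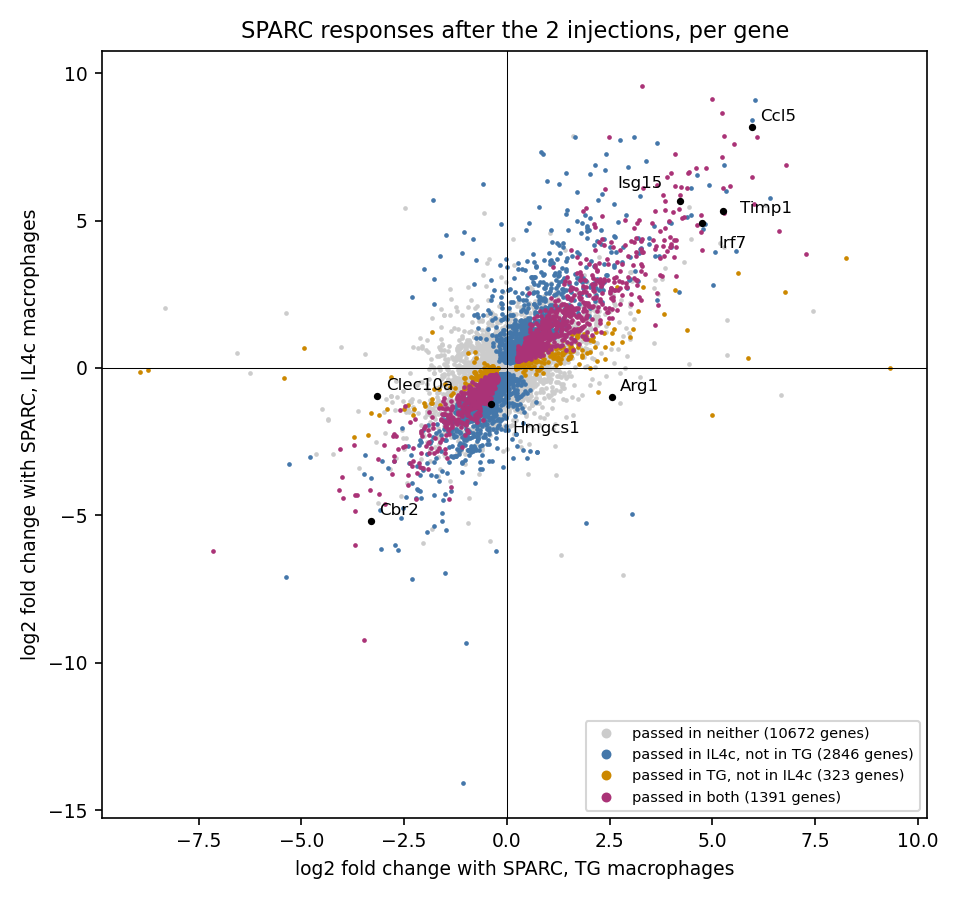
Log2 fold change with SPARC of each of the 15232 tested genes in TG (horizontal) and IL4c macrophages (vertical), coloured by the comparisons in which the gene passed, with named genes in black. The 1391 genes that passed in both lie along the diagonal, and Arg1 lies at 2.55 after TG and −0.98 after IL4c.

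No single gene passed the test of the difference between the responses: edgeR called 0 of 15232 genes, with a smallest adjusted p of 0.0616 and 1612 genes at an unadjusted p under 0.05. DESeq2 called 324 genes and limma-voom 0, while the replicate block in edgeR gave 472 (228 with a larger and 244 with a smaller value after IL4c). Without both TG libraries numbered 1 there were 836, without TG untreated replicate 1 there were 278 and without TG SPARC replicate 1 there were 84. Arg1 had a difference of −3.53 ± 0.63 (adjusted p = 0.147, and 0.0225 with the block), from a rise after TG and a value of −0.98 after IL4c. Without TG untreated replicate 1 its adjusted p was 0.0278.

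As lists, 9 of 31 sets differed between the responses by camera, and none of these passed with an estimated correlation. Cholesterol genes had the smallest p, with a median difference of −0.84, from a fall after IL4c and a median of 0.02 after TG (adjusted p = 4.36e-18; adjusted p = 0.205 with an estimated correlation). Of these 23 genes 14 had a smaller value adjusted over the list alone and 11 with the replicate block. Idi1 differed by −1.76 ± 0.31, Stard4 by −1.66 ± 0.30 and Hmgcs1 by −0.84 ± 0.13. These 3 genes had adjusted p = 0.147 each over all genes, and they passed with the block (adjusted p from 0.0149 to 0.0272) and without TG untreated replicate 1 (adjusted p from 0.00376 to 0.0274). Fatty acid oxidation genes had a median difference of −0.26 (adjusted p = 4.08e-04; adjusted p = 0.305 with an estimated correlation), with 7 lower adjusted over the list alone. Interferon-stimulated genes had a median difference of 0.78 toward a stronger rise after IL4c (adjusted p = 2.86e-12; adjusted p = 0.678 with an estimated correlation), with 13 higher adjusted over the list alone and 13 with the block. Without both TG libraries numbered 1 this median was 0.42, with 3 genes higher. Ifit1, an antiviral RNA-binding protein, differed by 2.21 ± 0.41, Oas3 by 1.72 ± 0.33 and Isg15 by 1.46 ± 0.29. Each missed the threshold over all genes (adjusted p of at most 0.159) and passed with the block (adjusted p from 0.0290 to 0.0434). Ifit1 and Oas3 also passed without TG untreated replicate 1. MHC class I genes had a median difference of 0.68 (adjusted p = 1.51e-07; adjusted p = 0.678 with an estimated correlation), with 7 higher adjusted over the list alone. H2-Q6, which shares reads with other H2-Q genes, differed by 3.52 ± 0.59 and H2-T22 by 1.33 ± 0.26, and both passed with the block (adjusted p = 7.17e-04 and 0.00852). With SPARC present after both injections, the level of the MHC class I list did not pass between them (median 0.11, camera adjusted p = 0.410). Glycolysis genes had a median difference of −0.37 (adjusted p = 0.00134; adjusted p = 0.678 with an estimated correlation), with 6 lower under the block. Liver X receptor targets had a median difference of 1.16 (adjusted p = 0.0354; adjusted p = 0.678 with an estimated correlation), including Nr1h3 at 1.85 ± 0.38 (adjusted p = 0.161), which passed without TG untreated replicate 1 (adjusted p = 0.00281). Without both TG libraries numbered 1, glycolysis and liver X receptor targets no longer passed (adjusted p = 0.0717 and 0.0960), nor did oxidative phosphorylation (adjusted p = 0.0960). The median of the liver X receptor targets was then 0.60. With the replicate block the alternative activation list also passed (adjusted p = 0.0121; adjusted p = 0.433 with an estimated correlation). So did B cell genes (adjusted p = 1.14e-04; adjusted p = 0.433 with an estimated correlation), cell cycle genes (adjusted p = 0.00731; adjusted p = 0.470 with an estimated correlation) and T and NK cell genes (adjusted p = 0.0413; adjusted p = 0.470 with an estimated correlation). Without the block these 4 lists did not pass (adjusted p from 0.224 to 0.440).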

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

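The tests of explanations in this part were chosen after the results were seen; the test of the difference was not. These lists were singled out because their responses to SPARC differed between the injections in the camera test of the difference, a call that no list kept with an estimated correlation. The median difference, IL4c minus TG, was 0.78 for interferon-stimulated genes and 0.68 for MHC class I presentation. It was −0.37 for glycolysis, −0.20 for the TCA cycle and −0.17 for nuclear oxidative phosphorylation genes. It was −0.26 for fatty acid oxidation, −0.84 for cholesterol synthesis and uptake and 1.16 for liver X receptor targets. For mesothelial genes, none of which reached 3 CPM, it was 2.43.

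With SPARC, 48 and 51 of 51 interferon-stimulated genes and 13 and 18 of 37 NF-kB genes rose in TG and IL4c macrophages. Library scaling moves all genes of a library alike and was excluded, since both list medians lay above the median of all genes by at least 1.13 in both injections. Whether neutrophils in the SPARC wells took part was not settled by their markers. S100a9, Ltf and Ngp reached at most 3 counts there beside 5984 to 68502 counts of Lcn2. However, S100a9 was as low in untreated libraries, where S100a8 had 210 to 482 counts, so it cannot decide. With SPARC, S100a8 had 936 to 1695 counts and Camp 8 to 85 (at most 6 untreated). Endotoxin or another microbial product in the added protein would raise the NF-kB list, whose median in IL4c macrophages was 1.77, and it cannot be told apart from SPARC itself without a control protein, so the rise may come from either.

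Mitochondrially encoded mRNAs, a set chosen after seeing the data, were lower with SPARC in IL4c macrophages for 11 of 13 genes, with a median of −2.59. Reads moved to nuclear copies were excluded, since the sum with those copies still fell by 1.58 in the IL4c pair with the smallest fall. In the 3 IL4c pairs the lowest value of the ribosomal mt-Rnr1 and mt-Rnr2 was −0.27, while the mRNAs together stood at −1.46 or lower. Less mitochondrial RNA of every kind was still not excluded, since the ribosomal counts also come from libraries selected for tails. Constant capture of these RNAs was not measured, and mt-Rnr1 itself rose by 0.97 to 1.19 in the IL4c pairs. A change in how well tails of mitochondrial mRNAs were captured could give the same median of −2.59, and it cannot be told apart from fewer transcripts with libraries all selected for tails. In TG macrophages 0 of 13 passed in edgeR (3 lower with the replicate block), and the difference between the injections did not pass for any of the 13 (5 with the block).

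Both TG libraries numbered 1 stood apart. B cells alone were excluded as the whole cause, since the large resident macrophage list lay above the other TG libraries by a median of at least 1.55 in both. Resident macrophages alone were excluded in the same way, since the B cell list lay above by at least 3.32. A different mix of several cell types may account for the pair, since 5 of 11 cell type lists deviated by a median beyond 1 in the same direction in both libraries: resident macrophages, B cells, T and NK cells and dendritic cells higher, fibroblasts and endothelium lower. Cell cycle genes were also higher in both for 32 of 35, and what set the mix apart stays open.

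In that pair Ighm stood at 1356 and 1257 CPM, and Il7r at 44.1 and 24.9 CPM against 386 to 873 CPM in the other TG libraries. Il7r belongs to the T and NK cell list and runs against it: the list lay higher in the pair by its median, with 13 of 14 genes higher in both libraries, while its sum was lower, at 66.7 and 63.5 CPM against 393 to 878 CPM.

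Libraries were also split in other ways. For each SPARC comparison only 1 of 10 splits, the real one, called as many genes, and the highest other called 0, also among the 4 that part all 3 pairs. Between the injections the real split was again 1 of 10, and the highest other called 1 gene. With 10 splits no share under 0.05 can be reached. For the difference between the responses the test is void: any draw must call at least as many genes as the real 0, and all 100 of 100 did. The highest other, 5341, came from swapping all TG labels, which by construction turns the shared response into a difference, a structure of the samples.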

How the results depend on the processing

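The 2 left-out pairs and the camera tests with the block or without the TG pair were chosen after the data were seen. In TG macrophages 505 genes passed with the compared groups alone, 4165 with the replicate block, 686 with a fold minimum of 2, and 737 to 2095 with single libraries left out. In IL4c macrophages the counts were 6880 with the block, 6507 without the TG pair numbered 1, 2679 without the IL4c pair numbered 3, 1733 with the fold minimum, and 2507 to 5178 with single libraries left out. Between the injections they were 1631 with the compared groups alone, 6002 without the TG pair, 1242 with the fold minimum and 1376 to 4562 with single libraries left out. There the number block, which pairs nothing across injections, gave 127. For the difference they were 2 by total counts, 324 by DESeq2, 2 without the filter, 3 with the strict filter, 16 and 3 on log2 FPKM with pseudocounts of 1 and 0.1, and 44 on FPKM without a filter. They were 472 with the block, 836 without the TG pair, 1 without the IL4c pair, and 0 to 278 with single libraries left out.

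Lists passing camera numbered 9 in TG and 8 in IL4c macrophages, 11 between the injections and 9 for the difference. With an estimated correlation each was 0. Fry gave 14 in IL4c macrophages, 6 between the injections and 2 for the difference. Camera with the replicate block gave 16 in IL4c macrophages and 12 in TG macrophages, where the monocyte, NRF2 and B cell lists were added. Further, camera without the TG pair gave 6 between the injections, where the interferon, GTPase, MHC class I, glycolysis, T and NK cell and mast cell lists lost their calls and that of fibroblasts and endothelium gained one. In TG macrophages it gave 11, without the matrix and unfolded protein response lists and with the monocyte, inflammasome, mesothelial and B cell lists, and for the difference 6, without the glycolysis, oxidative phosphorylation and liver X receptor lists. Without the TG pair the B cell list passed camera in both SPARC comparisons (adjusted p = 0.0445 and 0.00377). Camera without the pair was run with the preset correlation only. The correlation of the responses, 0.711, was 0.404 by DESeq2, 0.328 without the filter, 0.847 with the strict filter, 0.578 without the TG pair and 0.567 to 0.689 with single libraries left out. The sets without a filter hold more low-count genes and the strict set fewer.

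No called gene of the naming rule turned direction. Apart from the genes always named, they were chosen for large changes or small p in these same libraries. A turn was therefore unlikely beforehand. These values that had not passed did turn. In TG macrophages Il6 stood at −0.50 without the TG pair and ran from −0.27 to 3.03 with single libraries left out. Retnla stood at 0.0604 without the TG pair and ran from −0.99 to 0.77, Tlr4 from −0.14 to 0.0861 and Sparc from −0.38 to 0.75. In IL4c macrophages Sparc stood at −0.0231, −0.0146 and −0.0231 on the 3 FPKM settings and ran from −0.63 to 0.90, and Gata6 ran from −0.29 to 0.33. Between the injections Mrc1 stood at −0.0726, −0.0789 and −0.0726 on the FPKM settings and −0.71 without the IL4c pair, and ran from −0.74 to 0.73. Apart from changes that follow from fewer libraries or genes, the cause was not tested.

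Of the 33 TG and 37 IL4c calls on genes named beside these comparisons, the block kept all 33 and 37. For the SPARC comparisons and the difference it changed no other call on these genes than those given beside the results. Between the injections the number block kept 11 of 31 calls. The 10 genes named for the difference had not passed. All 10 passed with DESeq2 and without both TG libraries numbered 1, 9 with the block and 8 without TG untreated replicate 1. Apart from Arg1 they had been named for the smallest p of their lists in this comparison, so these passes are no independent support. DESeq2 also made 41 false calls among 141 in the TG simulation. With limma-voom 0 of them passed. With the compared groups alone 23, 36 and 26 calls were kept in TG, in IL4c and between the injections. Without the filter they were 29, 36 and 25, with limma-voom 32, 36 and 26, and on log2(FPKM + 1) 31, 37 and 28. Between the injections Lrg1, Ly6c2, Col1a1, Sparc and Tnf did not pass with the compared groups alone, nor Irf3 and these 5 without the filter. With limma-voom Rnase2a, Ackr3, Ly6c2, Col1a1 and Sparc did not pass, and on log2(FPKM + 1) Ly6c2, Col1a1 and Sparc. In TG macrophages Saa1, Ly6c2, Tnf and Il1b did not pass without the filter. With the compared groups alone Lcn2, Saa1, Ly6c2, Ly6i, Cbr2, Gas6, Il1b, Hsp90b1, Hyou1 and Tbk1 did not pass there. Without the TG pair Saa1, Tnf and Il1b did not pass. In IL4c macrophages mt-Co3, Hpgds and Tnf did not pass without the IL4c pair. Where a group keeps 2 libraries, the spread is pooled over the groups. Depth limits genes with few counts, such as Ifnb1 with 2 counts in all libraries together.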

Other observations

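The genes in this part were chosen after their values were seen. Ifng, the gene of interferon gamma, had 0 to 2 counts in untreated TG libraries and 44 to 107 counts in TG libraries with SPARC, a change of 6.77 ± 0.89 (adjusted p = 0.00439). The size of the change is uncertain so near the floor. It was 9.28 without TG untreated replicate 1, the only untreated TG library with counts. On log2(FPKM + 0.1) it was 4.06 and on log2(FPKM + 1) it was 1.48. In IL4c macrophages Ifng had at most 1 count per library, too few for an estimate of change. There edgeR gave 2.58 ± 1.64 (adjusted p = 0.285), limma-voom 0.84 and log2(FPKM + 0.1) values 0.18. The test of the difference between the injections (−4.18 ± 25.2, adjusted p = 0.984) is not informative with so few IL4c counts. It does not show that the 2 responses of Ifng were alike.

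With SPARC present in both, IL4c macrophages still differed from TG macrophages. Of 23 cholesterol genes 21 were lower after IL4c, with a median of −1.31 (camera adjusted p = 9.90e-16). Of 20 large resident macrophage genes 9 were higher, with a median of 2.40 (camera adjusted p = 1.81e-05). Of 51 interferon-stimulated genes 13 were higher, with a median of 0.41 (camera adjusted p = 0.00195). Of 21 interferon-gamma-type GTPases and targets 1 was higher and 3 lower, with a median of −1.03 (camera adjusted p = 0.0467). Of 30 alternative activation genes 10 were higher and 3 lower, with a median of 0.92 (camera adjusted p = 0.0296). Among lists of other cells the medians were −2.84 for T and NK cells (camera adjusted p = 0.00195), −2.04 for B cells (camera adjusted p = 0.0467) and 3.31 for mast cells (camera adjusted p = 0.0467). Of 14 monocyte and small macrophage genes 6 were lower, with a median of −0.71 (camera adjusted p = 0.0461). Several lists whose responses to SPARC had differed did not pass at these end levels. Medians were 0.11 for MHC class I presentation (camera adjusted p = 0.410) and −0.09 for glycolysis (camera adjusted p = 0.852). They were 0.08 for the TCA cycle, −0.01 for oxidative phosphorylation and 0.06 for fatty acid oxidation (camera adjusted p = 0.374, 0.852 and 0.834). With an estimated correlation no list passed (adjusted p = 0.294 for cholesterol and 0.948 for the others). Tests without libraries were chosen after the data were seen. Without TG SPARC replicate 1 the B cell, monocyte and mast cell lists did not pass (camera adjusted p = 0.581, 0.159 and 0.0667), and the B cell median was 0.11. Without both TG libraries numbered 1 the GTPase list did not pass either (camera adjusted p = 0.0549), while liver X receptor targets, which had not passed (camera adjusted p = 0.0630), did (camera adjusted p = 0.0113).

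The mitochondrial mt-Cytb fell with SPARC in IL4c macrophages from 1536 ± 431 to 225 ± 160 CPM, a change of −2.77 ± 0.51 (adjusted p = 0.00367). The ribosomal mt-Rnr1 stood at 1.08 ± 0.42 there (adjusted p = 0.0854) and rose by 1.93 ± 0.43 in TG macrophages (adjusted p = 0.0213). By pair, the TG value was 0.30 for the libraries numbered 1, and 2.41 and 2.59 for those numbered 2 and 3. The ribosomal mt-Rnr2 stood at −0.10 ± 0.20 in IL4c macrophages (adjusted p = 0.760). In TG macrophages mt-Rnr2 stood at 0.54 ± 0.20 (adjusted p = 0.115, and 0.0473 with the replicate block). Saa3, an acute-phase gene, took the most counts of any gene in all 3 IL4c libraries with SPARC and in TG SPARC replicate 1, from 2.40% to 3.61%.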
